A study of Sus scrofa with 12 samples.

How the data were processed

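Methylated RNA immunoprecipitation sequencing (MeRIP-seq) measured N6-methyladenosine (m6A), a methyl mark on adenosines in mRNA, together with mRNA levels. The cells were primary granulosa cells, the somatic cells that surround the oocyte in the ovarian follicle, recovered from crossbred sows (Sus scrofa). Per the labels, they were kept for 12 h in normoxia (21% O2) or hypoxia (1% O2). Each condition had 3 biological replicates, and each replicate gave an input library of fragmented poly(A) RNA and a library enriched with an m6A antibody (IP), 12 libraries in all. The labels name 1 batch for all samples and mark strand in the library preparation. Whether the replicates came from different sows is not given in the sources used here.

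The deposited expression table holds FPKM (fragments scaled by transcript length and library size) for 18060 genes in the 6 input libraries, per the file headers. Per the submitters' processing notes, the tools were fastp 0.19.4, FastQC, HISAT2 2.0.4, StringTie 2.1.2, edgeR 4.1 and HOMER 4.10, with the genome build Sscrofa11.1. Which tool made which table is not given in the sources used here. The authors' deposited expression comparison gives a log2 fold change, p-value and q-value per gene; the genes marked significant there all had an unadjusted p-value under 0.05 and at least a 2-fold change. The authors' deposited peak lists, 1 per condition, give each m6A peak's position, annotated region, log2 enrichment of IP over input, p-value and adjusted p-value. The listed peaks all had an unadjusted p-value under 0.05, and the highest adjusted p-value among them was 0.489 in normoxia and 0.532 in hypoxia. The authors' deposited table of differential peaks gives a log2 difference in m6A between hypoxia and normoxia with its p-value and adjusted p-value, and lists peaks with an unadjusted p-value under 0.05. The peak caller, and whether replicates were pooled or modelled together, are not given in the sources used here. The enrichments of peaks are the authors' values and are used here to describe and filter peaks within a list, and in 1 test in the closing section to compare the difference between regions of a list with that of the other list.

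The sign of the differential table was checked against the peak lists. Of its 519 peaks with a positive value, 87 overlapped a peak of the hypoxia list alone and 0 a peak of the normoxia list alone. Of the 687 with a negative value, 121 overlapped the normoxia list alone and 0 the hypoxia list alone. Positive values were therefore read as higher in hypoxia. In the normoxia list 3369 peaks begin 1 base before the annotated start of their gene and 0 begin at it, so starts were read as counted from 0 and are given here counted from 1, which is 1 more than in the deposited tables. Lengths in the deposited tables are 1 base longer than this reading gives. Peak spans run from first to last base and include introns.

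Gene symbols were those of the deposited tables for 13660 genes, and 120 more came from a table of gene names; 4280 genes kept an identifier only. Genes of the mitochondrial genome are not among those listed. FPKM holds no fragment counts. Low FPKM values were searched for the steps that whole reads would leave, and the most frequent ratio between normoxia libraries 1 and 2 was shared by 4 of 607 low genes, so the depth of each library is unknown. No counting interval or floor is given for this reason. The FPKM of a library summed to between 294929 and 326804.

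The input RNA of the 3 hypoxia libraries was compared with that of the 3 normoxia libraries with limma 3.58.1 in R 4.3.3, with a variance trend and robust estimation, on log2(FPKM + 1). Genes with at least 1 FPKM in at least 3 libraries were tested, and p-values were adjusted with the Benjamini-Hochberg method. A fold change is given on the log2(FPKM + 1) scale unless FPKM are compared directly; this scale understates the change of genes with low FPKM. Errors are the SD over 3 libraries for FPKM and the SE of the limma fit for log2 fold changes. FPKM were used as deposited, and a median-ratio factor per library was the alternative scaling. On simulated values for the 10196 tested genes, with 100 genes changed by 1 log2 unit and 100 by 2, the test recovered 57% and 83% of them, with 6 false calls among 146. The simulated noise was independent between genes, and 200 genes changed in all. Real libraries share deviations across genes and far more genes passed, so these rates need not hold for the real test.

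Gene lists were tested with camera at a preset inter-gene correlation of 0.01, which compares a list with all other genes, and with the correlation estimated per list. Fry, which asks whether a list changed without comparing it with other genes, was run beside it. The adjustment was over the lists with at least 3 tested members. The lists were glycolysis and glucose uptake, HIF-responsive genes outside glycolysis, m6A writers, erasers and readers, NAD+ synthesis and salvage, NAD+ consumption, steroidogenesis, cholesterol synthesis, granulosa cell identity, ovulation and luteinization, nuclear genes of oxidative phosphorylation, the tricarboxylic acid cycle, G2 and mitosis, DNA replication, the integrated stress and unfolded protein response, p53 targets and apoptosis, antioxidant genes, and extracellular matrix. Lists of markers covered theca, fibroblast and smooth muscle, endothelial, leukocyte, oocyte and erythrocyte cells, and the last list held genes of the mitochondrial genome. The lists, the tests and the rule for named genes were fixed before the data were examined.

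The rule named FTO, ALKBH5, METTL3, METTL14, NMNAT1, NMNAT2, NMNAT3 and NAMPT, and the 8 genes with the largest rise and the 8 with the largest fall among genes past the threshold whose values did not overlap between conditions. It also named up to 4 members of each list by smallest adjusted p, with 1 that went against its list. For peaks it named those of FTO and NMNAT3, the 6 differential peaks with the largest positive and the 6 with the largest negative value, up to 3 genes per list with a differential peak, and 2 genes for each pairing of m6A and RNA direction. Names outside this rule are said to have been chosen after their values were seen.

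Peaks of the conditions were compared with bedtools 2.31.1, requiring 1 shared base on the same strand. Two-sided Fisher's exact tests compared directions and positions, a Mantel-Haenszel odds ratio held the RNA fold change in classes (added after the data were seen), and Spearman correlations used 100000 permutations. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used. The alternatives tried were other pseudocounts (0.1 and 0.01), no filter or a filter at 5 FPKM, median-ratio scaling, limma without its trend, a 2-fold threshold, the replicate number as a block, each library left out in turn, stricter thresholds for peaks, and a reciprocal overlap of 50%. Limma quality weights, removal of a trend with gene density, and leaving out both libraries numbered 3 were added after the data were seen, as were tests of KEGG pathways. Comparing IP with input per gene and library was not done, since FPKM of IP libraries were not used here. Searching peaks for the DRACH motif and measuring distances to stop codons need a genome sequence and annotation, which were not used here.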

Results

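The 8 genes with the largest rise in hypoxic porcine granulosa cells (3 input libraries per condition) were MT1A, CALY, CPNE6, SLC16A3, SLC2A5, CXCL14, APLN and BNIP3. The metallothionein gene MT1A, whose product binds zinc and copper, had 0.192 ± 0.259 FPKM in normoxia and 175.5 ± 118 in hypoxia (mean ± SD), a log2 fold change of 7.03 (SE 0.44, limma adjusted p = 0.00023). CALY, which codes for a vesicle-trafficking protein, reached 117 ± 37.9 FPKM (log2 fold change 6.67, SE 0.244). CPNE6, which codes for a calcium-dependent membrane-binding protein, was listed at 0 in each normoxia library and at 85.2, 67.5 and 139 FPKM in hypoxia. The lactate exporter SLC16A3 rose from 0.950 ± 0.283 to 113 ± 28.6 FPKM (log2 fold change 5.85, SE 0.216, adjusted p = 4.36e-05), and the fructose transporter SLC2A5 from 0.419 ± 0.108 to 55.3 ± 3.06 (5.31, SE 0.145, adjusted p = 1.5e-05). The chemokine gene CXCL14 (5.27, SE 0.338), the peptide hormone gene APLN (5.11, SE 0.292) and the mitophagy receptor gene BNIP3 (4.61, SE 0.146) completed the 8 largest rises; BNIP3 reached 899 ± 85 FPKM.

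The 8 genes with the largest fall were CCL2, SLC43A2, NPC1, MARS1, SPSB2, SELENOS, LIPG and NUPR1. CCL2, a chemokine that draws monocytes, fell from 401 ± 192 to 20.9 ± 8.8 FPKM (log2 fold change -4.17, SE 0.383, limma adjusted p = 0.000789). The amino acid transporter SLC43A2 (-2.92, SE 0.222), the lysosomal cholesterol exporter NPC1 (-2.89, SE 0.164, 1.51 ± 0.322 FPKM in hypoxia) and the methionyl-tRNA synthetase MARS1 (-2.64) followed. SPSB2, an adaptor for ubiquitination, changed by -2.61, the endoplasmic reticulum selenoprotein gene SELENOS by -2.51, the lipase gene LIPG by -2.50 and the stress-response gene NUPR1 by -2.50 (550 ± 79.2 to 96.3 ± 8.01 FPKM). These 8 falls and the 8 rises above stayed past the threshold with each library left out and after median-ratio scaling.

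Of 10196 tested genes, 2699 passed an adjusted p of 0.05, 551 (20.4%) higher and 2148 (79.6%) lower in hypoxia. The median log2 fold change over all tested genes was -0.26, so medians of gene lists are also given relative to it. After median-ratio scaling 1719 genes passed, 818 (47.6%) higher and 901 (52.4%) lower, and 1451 passed in the same direction under both. Values of the conditions did not overlap for 4501 of the tested genes (44.1%), where chance gives 10%. The count was 1132 without normoxia library 2, 1394 without normoxia library 3, 1546 without normoxia library 1, 1420 without hypoxia library 1 and 4329 without hypoxia library 3. The authors' deposited table marks 2432 genes, 858 up and 1574 down. Of the 1781 marked genes tested here, 1617 were also called here, each in the same direction. At a q-value under 0.05 alone that table holds 2479 genes, with a near-even 1236 higher and 1243 lower.

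The m6A erasers FTO and ALKBH5 went in opposite directions. The demethylase gene FTO had 19.0 ± 1.15 FPKM in normoxia and 13.1 ± 1.79 in hypoxia (log2 fold change -0.51, SE 0.152, limma adjusted p = 0.0457). After median-ratio scaling its log2 fold change was -0.21 (adjusted p = 0.53), and its call was lost without hypoxia library 1 (0.159) or 2 (0.0934) and without normoxia library 1 (0.108), 2 (0.156) or 3 (0.167). The demethylase gene ALKBH5 had 10.1 ± 0.723 and 16.7 ± 1.06 FPKM (0.67, SE 0.139, adjusted p = 0.0125, 0.97 after scaling). Its adjusted p was 0.0523 without hypoxia library 1, and 0.0605, 0.0546 and 0.0612 without normoxia libraries 1, 2 and 3. The methyltransferase gene METTL3 had 6.44 ± 0.352 and 4.62 ± 0.486 FPKM (-0.41, adjusted p = 0.089) and its partner METTL14 1.84 ± 0.175 and 2.06 ± 1.21 (0.03, adjusted p = 0.953). Of 10 tested writers 0 passed limma (1 at an unadjusted p under 0.05), and the list had a median of -0.22 (camera adjusted p = 0.964); the 10 readers had a median of -0.28 (0.860). Among readers IGF2BP2, which binds methylated mRNA, had a log2 fold change of 0.85 (adjusted p = 0.01003, 0.0522 without normoxia library 2 and 0.0509 without 3). ELAVL1 had -0.92 (adjusted p = 0.0236, 0.069 after scaling, 0.0576 without hypoxia library 1 and 0.091, 0.0977 and 0.0638 without normoxia libraries 1, 2 and 3).

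Of 9 tested genes of NAD+ synthesis, NMNAT3, NADSYN1 and NAPRT were higher in hypoxia and NMNAT2 and NADK lower. NMNAT3, which makes NAD+ from nicotinamide mononucleotide, had 0.121 ± 0.0358 FPKM in normoxia and 5.36 ± 0.973 in hypoxia, a ratio of 44.3 (log2 fold change 2.49, SE 0.170, limma adjusted p = 0.00025); its highest adjusted p with a library left out was 0.00573. NADSYN1, the NAD+ synthetase gene, rose from 3.92 ± 0.694 FPKM (log2 fold change 1.39, SE 0.193, adjusted p = 0.00308) and NAPRT, which uses nicotinic acid, from 8.92 ± 1.88 (1.65, SE 0.302, adjusted p = 0.00855). NMNAT2 fell from 8.76 ± 0.283 to 4.80 ± 0.384 FPKM (-0.75, SE 0.142, adjusted p = 0.00886), but had -0.47 (adjusted p = 0.0617) after median-ratio scaling and 0.052 without normoxia library 2. NMNAT1 (1.01 ± 0.275 and 0.719 ± 0.264 FPKM) and NAMPT (0.849 ± 0.131 and 1.74 ± 0.91) were too low to be tested. The list counts of 3 higher and 2 lower (4 and 2 when adjusted over the list alone, 4 and 0 after scaling) went with a median of 0.29, or 0.56 relative to all genes (camera adjusted p = 0.0152, adjusted p = 0.221 with an estimated correlation). NADK had -0.66 (adjusted p = 0.0118, 0.141 after scaling) and was chosen after its values were seen. Of 12 genes of NAD+ consumption 3 were lower (3 over the list alone, 1 after scaling), with a median of -0.40 (camera adjusted p = 0.757). PARP1, a DNA repair enzyme that consumes NAD+, fell from 24.1 ± 2.36 to 12.4 ± 1.06 FPKM (-0.90, SE 0.148, adjusted p = 0.00541).

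**Figure D1:**
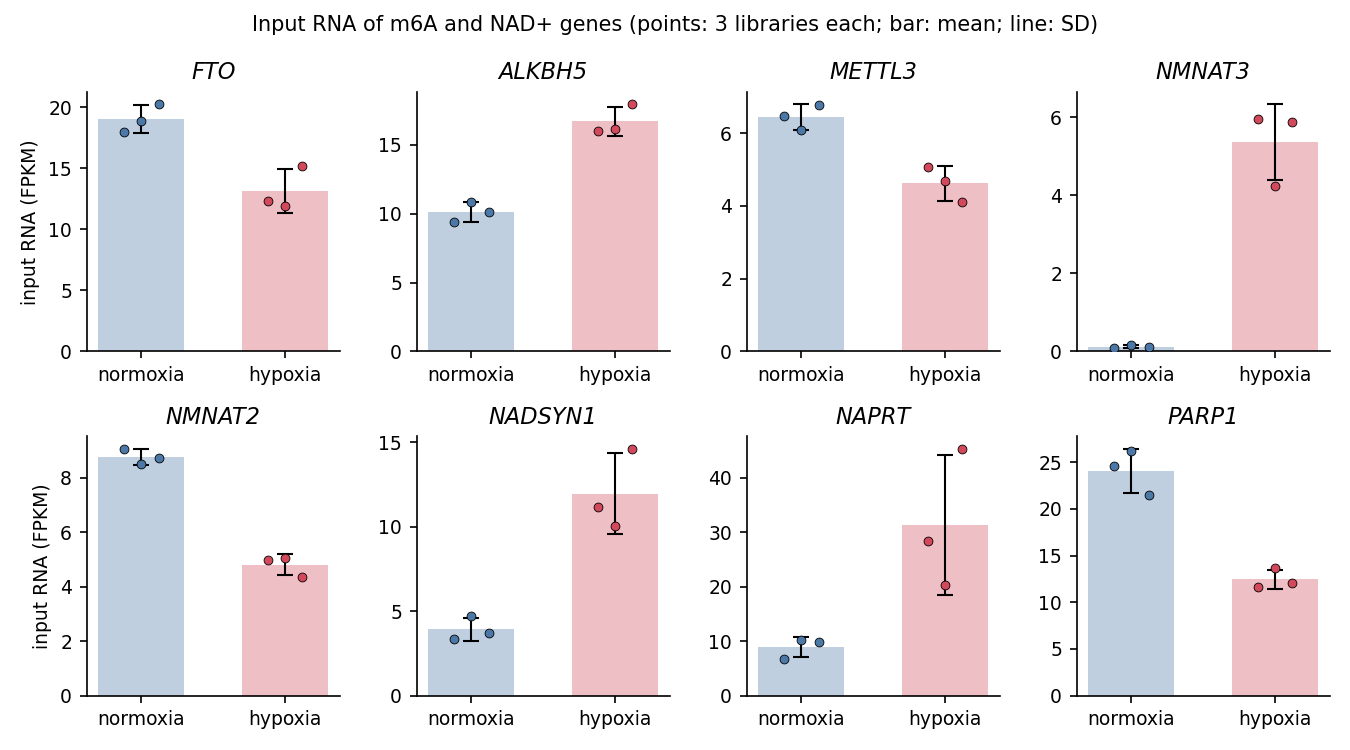
FPKM of m6A and NAD+ genes in input RNA of normoxia and hypoxia; points are the 3 libraries of a condition, bars the mean and lines the SD. NMNAT3 had 0.121 FPKM in normoxia and 5.36 in hypoxia.

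Each tested gene of glycolysis and glucose uptake was higher in hypoxia (22 of 22, 22 over the list alone and 22 after median-ratio scaling). The median log2 fold change of the list was 2.06, or 2.32 relative to all genes (camera adjusted p = 8.05e-30, adjusted p = 0.0504 with an estimated correlation). HK2, which phosphorylates glucose, rose from 6.36 ± 0.28 to 36.7 ± 1.87 FPKM (log2 fold change 2.36), ALDOC, a fructose-bisphosphate aldolase, reached 140 ± 22.5 (3.66), and the glucose transporter SLC2A1 rose from 23.8 ± 1.12 to 171 ± 37 (2.77). Among 34 genes that respond to hypoxia-inducible factors (HIF) outside glycolysis, 24 were higher and 2 lower (26 and 2 over the list alone, 26 and 1 after scaling). The list median was 1.61, or 1.87 relative to all genes (camera adjusted p = 3.95e-24), and this is the list whose call held with an estimated correlation (0.00558). DDIT4, an inhibitor of mTOR, rose from 22.4 ± 1.35 to 361 ± 99.2 FPKM (3.92), the angiogenic factor gene VEGFA from 9.91 ± 2.85 to 138 ± 17.4 (3.70), and ANKRD37 to 7.94 ± 1.63 (2.90). JMJD6, an oxygen-dependent hydroxylase, fell to 1.70 ± 0.256 FPKM (-0.97, limma adjusted p = 0.00501); the other lower gene, RAB20, had -0.92 (adjusted p = 0.0321, 0.117 after scaling) and was chosen after its values were seen.

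Of 65 nuclear genes of oxidative phosphorylation 29 were lower in hypoxia (34 over the list alone), and 6 after median-ratio scaling. The list median was -0.52, or -0.26 relative to all genes (camera adjusted p = 0.000107, adjusted p = 0.441 with an estimated correlation). ATP5MC1, a subunit of ATP synthase, fell to 30.3 ± 4.24 FPKM (log2 fold change -1.61, limma adjusted p = 0.000812), and subunits of complexes I and III fell as well: NDUFA6 -1.34, UQCRC1 -1.38 and CYC1 -1.28. In the tricarboxylic acid cycle 10 of 21 genes were lower (11 over the list alone, 3 after scaling), with a median of -0.59, or -0.33 relative to all genes (camera adjusted p = 0.0178, adjusted p = 0.375 with an estimated correlation). The malate dehydrogenase gene MDH2 fell from 177 ± 13.9 to 65.3 ± 1.19 FPKM (-1.42, adjusted p = 0.000682) and DLST, a subunit of oxoglutarate dehydrogenase, changed by -1.16. The 4 succinate dehydrogenase genes SDHA, SDHB, SDHC and SDHD are in both lists.

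Single genes of cholesterol synthesis, DNA replication and the integrated stress response fell, among them FDPS, MCM2 and ASNS. FDPS, which makes farnesyl diphosphate, fell to 9.79 ± 1.7 FPKM (log2 fold change -2.30, limma adjusted p = 0.000269), with MVD at -1.41, SQLE at -1.61 and SREBF2, the transcription factor of the pathway, at -1.59. Of 20 cholesterol genes 10 were lower (13 over the list alone, 6 after median-ratio scaling), with a median of -0.71, or -0.44 relative to all genes (camera adjusted p = 0.00454, adjusted p = 0.167 with an estimated correlation). The replicative helicase gene MCM2 fell from 15.0 ± 1.91 to 5.10 ± 0.721 FPKM (-1.39, adjusted p = 0.0017), with MCM7 at -0.94, GINS2 at -1.08 and CDT1 at -1.02. Of 19 replication genes 12 were lower (15 over the list alone); after scaling 10 were lower and 1, MCM4 (0.80, adjusted p = 0.0431), higher; MCM4 was chosen after its values were seen. Their median was -0.91, or -0.64 relative to all genes (camera adjusted p = 0.000775, adjusted p = 0.554 with an estimated correlation). The asparagine synthetase gene ASNS fell from 130 ± 5.08 to 32.3 ± 7.58 FPKM (-2.01, adjusted p = 0.000929) and the serine synthesis gene PSAT1 from 65.6 ± 11.4 to 11.6 ± 3.94 (-2.44), with SHMT2 at -1.54 and SLC3A2 at -1.33. Of 23 stress-response genes 12 were lower and 1 higher (12 and 1 over the list alone, 9 and 2 after scaling), with a median of -0.72, or -0.46 relative to all genes (camera adjusted p = 0.0178, adjusted p = 0.351 with an estimated correlation). EDEM1, which went against this list, had 0.90 (adjusted p = 0.0235, 0.0951 without hypoxia library 1, and 0.0622, 0.1002 and 0.0873 without normoxia libraries 1, 2 and 3).

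Of 18 tested genes of the extracellular matrix, LOXL2, COL5A1, COL1A1 and TIMP3 were higher in hypoxia. LOXL2, which crosslinks collagen, rose from 133 ± 12.9 to 468 ± 104 FPKM (log2 fold change 1.79, limma adjusted p = 0.00105). COL5A1 had 0.84 (adjusted p = 0.0114, 0.0553 without normoxia library 1 and 0.0552 without 3) and COL1A1 0.62 (adjusted p = 0.0259, 0.102, 0.0942 and 0.0884 without normoxia libraries 1, 2 and 3). TIMP3 had 1.25 (adjusted p = 0.0478), with 0.153 and 0.0703 without hypoxia libraries 1 and 2 and 0.123, 0.129 and 0.142 without normoxia libraries 1, 2 and 3. The 4 higher matrix genes (3 over the list alone, 7 after median-ratio scaling) went with a list median of 0.29, or 0.56 relative to all genes (camera adjusted p = 1.23e-05, adjusted p = 0.351 with an estimated correlation). Of the lists past camera, this one did not pass fry (fry adjusted p = 0.0576). INHBB, a subunit of inhibin B, rose from 16.4 ± 1.35 FPKM (0.90, adjusted p = 0.00429). The receptor gene FSHR had 9.74 ± 0.692 and 5.52 ± 0.257 FPKM (-0.72, adjusted p = 0.0101, 0.103 after scaling, 0.0547 without hypoxia library 1 and 0.0591 without normoxia library 3). The prostaglandin E synthase gene PTGES rose to 206 ± 45.6 FPKM (4.14, adjusted p = 0.000107), and the steroidogenic genes POR (-1.53, adjusted p = 0.00155) and SOAT1 (-1.53, adjusted p = 0.00239) fell. The cholesterol-binding protein gene TSPO, the 1 higher gene of 14 steroidogenic genes, had 36.6 ± 7.37 and 90.5 ± 31.9 FPKM (1.25, adjusted p = 0.0176, 0.0631 without hypoxia library 1 and 0.0701 and 0.0605 without normoxia libraries 1 and 2).

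Other lists did not pass camera. Granulosa identity had a median of -0.19 (adjusted p = 0.860), with 1 gene of 16 higher and 2 lower (1 and 2 over the list alone, 3 and 0 after median-ratio scaling). Steroidogenesis had -0.53 (0.221), with 1 of 14 higher and 4 lower (1 and 7, then 1 and 3). Ovulation and luteinization had -0.25 (0.860, 1 and 2 of 9, then 1 and 3, and 1 and 0) and p53 targets -0.18 (0.860, 1 and 3 of 15, then 1 and 3, and 1 and 0). G2 and mitosis had -0.41 (0.860), where UBE2C, a ubiquitin-conjugating enzyme of mitosis, was the 1 lower gene of 18 (0 over the list alone and 0 after scaling, 3 at an unadjusted p under 0.05, log2 fold change -1.03, limma adjusted p = 0.047). UBE2C had 0.113 after scaling, 0.0891 without hypoxia library 1, and 0.151, 0.172 and 0.0583 without normoxia libraries 1, 2 and 3. Antioxidant genes had -0.50 (0.173), with 5 of 18 lower (7 over the list alone, 1 higher and 1 lower after scaling). The higher one, PRDX1 (0.73, adjusted p = 0.0218 after scaling), was chosen after its values were seen. Without hypoxia library 3, steroidogenesis (0.0403) and antioxidant genes (0.0476) passed. The lower antioxidant genes included the thioredoxin reductase gene TXNRD1, which fell from 59.4 ± 5.41 to 15.0 ± 6.65 FPKM (log2 fold change -2.01, limma adjusted p = 0.00536). Among markers of other cells, those of fibroblasts and smooth muscle had a median of -0.22 (0.689, 2 higher and 2 lower of 10, with 2, COL1A1 and COL3A1, also in the matrix list), with the actin gene ACTA2 falling from 7642 ± 998 to 3477 ± 612 FPKM (-1.14, adjusted p = 0.00456). The fibroblast marker PDGFRA had 4.33 ± 0.651 and 8.50 ± 1.14 FPKM (0.84, adjusted p = 0.0121, 0.00545 after scaling, 0.0539 without hypoxia library 1 and 0.068 without normoxia library 2). The smooth muscle gene DES had -0.65 (adjusted p = 0.0492, 0.249 after scaling, 0.185 and 0.0699 without hypoxia libraries 1 and 2, and 0.0638, 0.191 and 0.162 without normoxia libraries 1, 2 and 3). Leukocyte markers had 0.60 (0.278, with 0 of 3 past limma and 0 at an unadjusted p under 0.05). The endothelial marker PECAM1 fell from 6.56 to 2.81 FPKM (-0.99, limma adjusted p = 0.00414). It was the 1 tested of 8 listed endothelial markers. The others had a mean of at most 0.324 FPKM in either condition, so PECAM1 alone does not show a change in endothelial cells. The theca markers PTCH1 and PDGFRB had -0.35 and 0.66 and the oocyte marker GDF9 -0.16, and these did not pass. Erythrocyte markers were too low to be tested.

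**Figure D2:**
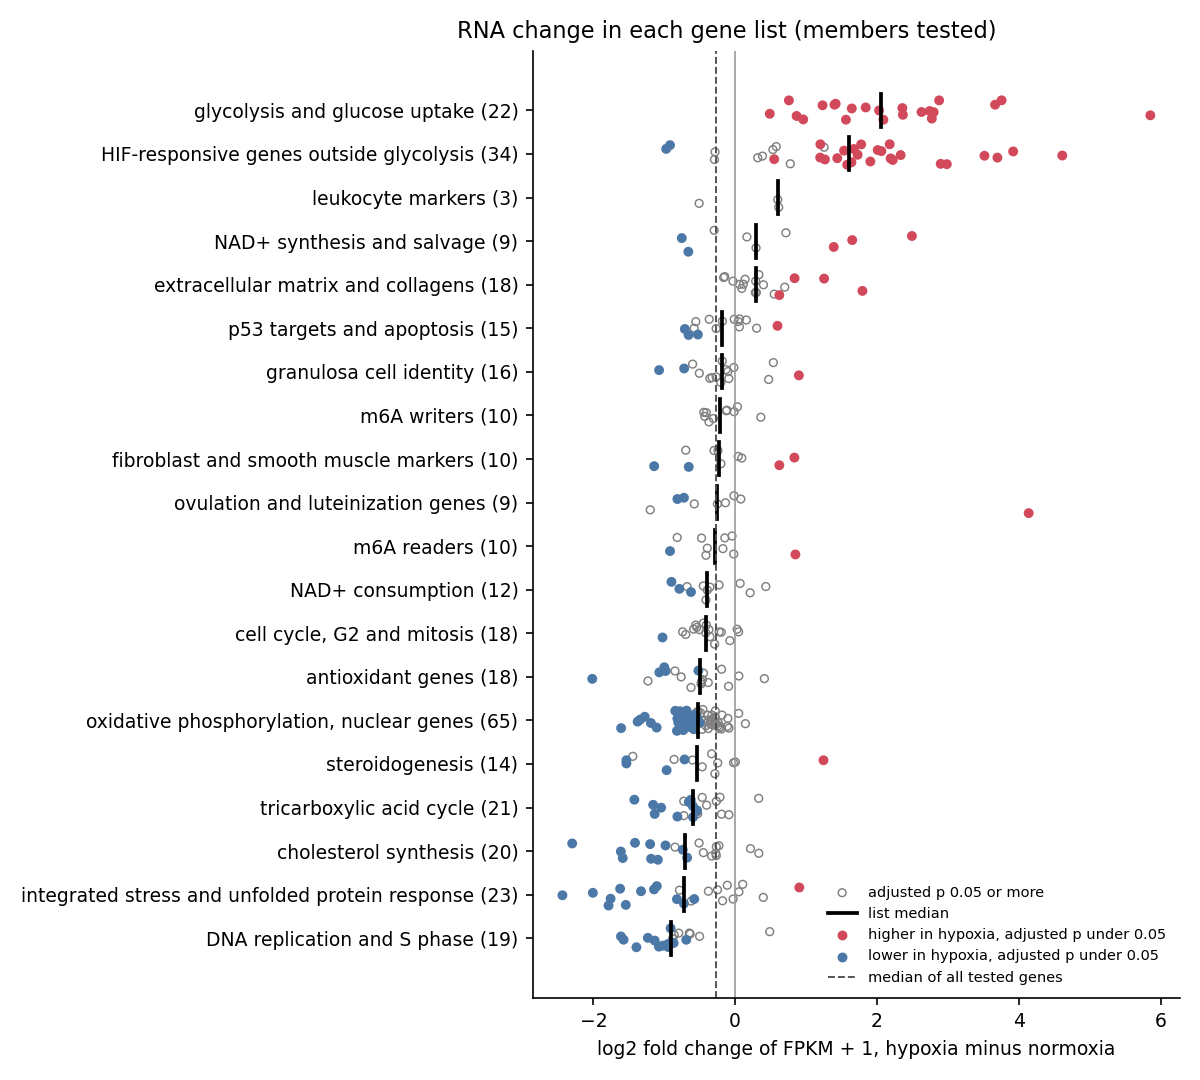
Log2 fold change of FPKM + 1, hypoxia over normoxia, for tested members of each gene list with at least 3; red points are higher and blue points lower at adjusted p under 0.05, open points are the rest, bars are list medians and the dashed line is the median of all tested genes (-0.26). Glycolysis had a median of 2.06 and DNA replication of -0.91.

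The deposited m6A peak lists covered FTO in both conditions and NMNAT3 in hypoxia. FTO had 1 exonic peak in normoxia (chromosome 6, 31427707 to 31458744, enrichment 3.9) and 1 in hypoxia (31427677 to 31564629, 5.04), and no differential peak. NMNAT3 had no peak in normoxia, where its RNA was 0.121 FPKM, and 2 peaks in the 3′ UTR in hypoxia (chromosome 13, 80431099 to 80431934, enrichment 6.13, 80432053 to 80432262, 1.8). The normoxia list held 25346 peaks in 11602 genes and the hypoxia list 24444 in 11047, with median enrichments of 4.23 and 4.81. Enrichments piled up at repeated values, with 831 normoxia peaks at 7.4 and 970 hypoxia peaks at 7.22, which a 4-fold filter keeps. The 10 most frequent values held 4885 and 5412 peaks. Among peaks of genes with the lowest RNA they made up 43.8% and 51.0%, against 12.8% and 14.5% of other peaks. Of these peaks 45.8% and 43.7% lay in 3′ UTRs, 32.8% and 35.8% in regions annotated as exonic, and 17.1% and 15.9% in 5′ UTRs. At least 1 base was shared by 18389 normoxia peaks (72.6%) and 20532 hypoxia peaks (84.0%) with the other list. A reciprocal overlap of 50% gave 43.4% and 44.9%, and both lists at 4-fold enrichment 73.95% and 73.98%, so the gap between conditions depends on the rule. Peaks also differed in length, with median spans (introns included) of 687 bases in normoxia and 449 in hypoxia. By gene, 10167 genes had a peak in both, 1435 in normoxia alone and 880 in hypoxia alone.

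The authors' deposited table of differential peaks listed 519 peaks higher and 687 lower in hypoxia, in 1095 genes, at an unadjusted p under 0.05; 426 had an adjusted p under 0.05 (224 higher, 202 lower). In the authors' deposited table, NMNAT3 had a 3′ UTR peak with a log2 difference of 1.30 (chromosome 13, 80431397 to 80431934, p-value 0.01 from that table, adjusted 0.125). The most positive values there were those of GPR75 (4.49, adjusted 0.103), HPDL (2.65, 0.122), ST14 (2.64, 0.257), LRIF1 (2.64, 0.249), PANK1 (2.60, 0.285) and LGI2 (2.44, 0.221), the last 5 with RNA under 1 FPKM in both conditions. The most negative were NEK2 (-4.70, adjusted 0.154), UCHL1 (-3.85, 0.00309), ABCF3 (-3.64, 0.270), TMEM184A (-3.58, 0.278), INMT (-3.51, 0.225) and TRIM37 (-3.26, 0.162), of which TMEM184A and INMT had RNA under 1 FPKM in both conditions. Among genes of the lists, the deposited table gives SLC2A1 1.10 (adjusted 1e-05), GYS1, a glycogen synthase, -0.39 (8.51e-06), HK1 0.33 (0.00288), P4HA1 0.29 (0.00479), PARP1 0.43 (0.0324) and YTHDF1 -0.35 (0.0832). Of the tricarboxylic acid cycle it gives OGDH 0.39 (adjusted 6.92e-08), DLD 0.27 (0.00316) and CS 0.48 (0.00759), with 3 peaks higher and 1 lower in that list, and of oxidative phosphorylation NDUFA6 0.48 (0.00138) and NDUFS1 -0.73 (0.152). The cholesterol genes FDFT1 (-0.30, adjusted 0.0398), NSDHL (-0.64, 0.0692) and MVD (-0.57, 0.0741) had lower values in the deposited table, as had the granulosa genes FOXO1 (-0.51, 0.0316), FSHR (-0.55, 0.0417) and GATA4 (-0.25, 0.0537). The deposited table also gives PDIA4 0.24 (adjusted 1.58e-34), ASNS -0.61 (0.154), DDIT3 0.26 (0.277), TXNRD1 -0.88 (0.112), POSTN 0.70 (0.0174), LAMC1 0.67 (0.0011), DCN 0.67 (0.00162), PECAM1 -0.55 (0.0229), E2F1 -1.15 (0.0603) and CD68 -1.59 (0.244).

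Peaks lower in hypoxia lay in 3′ UTRs more often than peaks higher in hypoxia. Among the lower peaks of the deposited table, 424 of 687 (61.7%) were in 3′ UTRs, against 206 of 519 (39.7%) of the higher peaks (odds ratio 2.45, 95% interval 1.93 to 3.12, Fisher's exact p = 3.18e-14). Among peaks that changed at least 2-fold the odds ratio was 1.36 (0.707 to 2.62, Fisher's exact p = 0.353). The higher peaks were in 5′ UTRs in 24.5% of cases and the lower ones in 14.4%. Peaks are not independent replicates, and some share a gene (1206 peaks in 1095 genes). The intervals and p-values of these odds ratios therefore do not measure the spread over the 3 replicates.

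**Figure D3:**
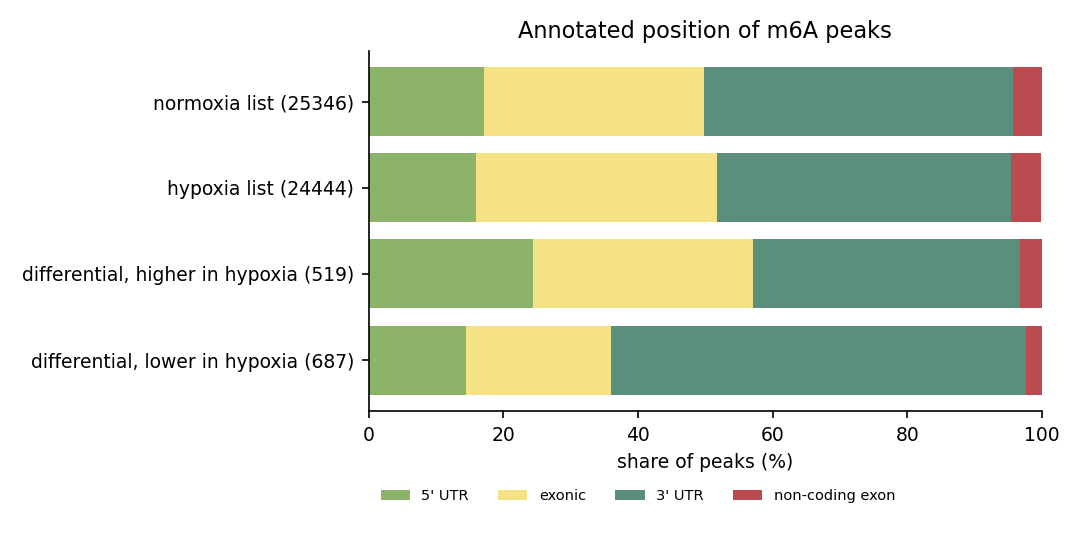
Share of m6A peaks by annotated region, in percent, for the normoxia and hypoxia lists and for differential peaks higher and lower in hypoxia; each bar is all peaks of that set. 3′ UTRs held 39.7% of higher and 61.7% of lower differential peaks.

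The deposited m6A differences were set beside RNA changes in 981 genes. EPAS1, which codes for the hypoxia-inducible factor HIF-2α, had a log2 m6A difference of 1.47 in the deposited table, and its RNA fell from 31.7 to 9.71 FPKM (log2 fold change -1.63, SE 0.242, limma adjusted p = 0.00408). Both values were higher for the carboxypeptidase gene CPM (m6A 0.89 in the deposited table, RNA 1.15) and the elongation factor gene EEF2 (0.18 and 0.55), and ABCF1 had higher m6A with lower RNA (0.37 and -1.17). In the deposited table m6A was lower with higher RNA for IL10RA (-0.33 and 1.40) and GYS1 (-0.39 and 1.64), and lower with lower RNA for LRRC8D (-0.71 and -1.81) and LRP3 (-0.59 and -1.54). SLC2A1 had higher m6A (adjusted p = 1e-05 in the deposited table) and higher RNA. NMNAT3 also had higher values of both, but its m6A difference had an adjusted p of 0.125 there. Its normoxia RNA was 0.121 FPKM, which leaves little input for a normoxia m6A level. Of 981 genes with both values, 426 passed both thresholds: 48 higher in both, 120 with higher m6A and lower RNA, 24 with lower m6A and higher RNA and 234 lower in both. After median-ratio scaling of the RNA these counts were 66, 40, 35 and 100. RNA was higher in 28.6% of genes with higher m6A and in 9.30% of those with lower m6A (odds ratio 3.89, 2.21 to 6.98, Fisher's exact p = 3.33e-07). After scaling the shares were 62.3% and 25.9% (odds ratio 4.68, Fisher's exact p = 2.23e-08). Across the 981 genes the Spearman rho was 0.24 (permutation p = 1e-05, the smallest the permutations can give). The m6A difference and the RNA change share the input libraries, so the odds ratio and rho without any link between them need not be 1 and 0. Those no-change values could not be computed without IP values per library, and genes are not independent replicates, so the p-values do not show a link between m6A and RNA.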

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

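Limma quality weights, removal of the trend with gene density, leaving out both libraries numbered 3, and median-ratio scaling in the list tests and in the comparison of m6A with RNA were chosen after the data were seen. Against 2699 genes changed in input RNA, median-ratio scaling gave 1719 (901 lower), a 2-fold threshold 1077 (338 higher, 739 lower), quality weights, whose fit stopped before convergence, 7455 (1955 higher, 5500 lower), and leaving out both libraries numbered 3 gave 4249 (1056 higher). With the density trend removed 1211 were higher and 1348 lower. With the replicate number as a block 3463 genes passed. Deviations of same-numbered libraries correlated at 0.586, 0.0398 and 0.697, but normoxia library 1 was closest to hypoxia library 2 (0.641). Deviations among 3 libraries are not independent, so these values cannot decide whether the numbers pair the libraries. With 1 library left out the count ran from 1132 to 4329, higher from 334 to 1143 and lower from 798 to 3186; it was 1132 without normoxia library 2, 1394 without 3 and 1546 without 1, and 1420, 2899 and 4329 without hypoxia libraries 1, 2 and 3. The 2-fold counts follow from the stricter threshold, and for the others the cause was not tested.

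Of 9 gene lists past the camera threshold, 1 (HIF-responsive genes) remained with an estimated correlation. For NAD+ synthesis (-0.085) and cholesterol synthesis (-0.022) the estimate lay below the preset 0.01. The loss of these 2 calls therefore does not come from a larger correlation. HIF-responsive genes had an estimate of -0.021, also below the preset value, and their unadjusted camera p still went from 3.95e-25 to 0.000279. The estimated setting thus weakens a call even without a larger correlation. A call lost under it in another list therefore does not by itself show correlated genes. With 1 library left out 9 to 11 lists passed, with steroidogenesis (camera adjusted p = 0.0403) and antioxidant genes (0.0476) added without hypoxia library 3. Of 82 named genes past the threshold, 33 were lost under at least 1 other setting and 28 with libraries left out, and 0 turned in direction with a call. The 2-fold threshold, which ends calls by its stricter rule, lost 30 genes. Median-ratio scaling lost 19 and removal of the density trend 14, and these sets can overlap.

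At 4-fold enrichment 13269 normoxia and 14852 hypoxia peaks remained, with 49.1% and 45.3% in 3′ UTRs, and at p of 1e-10 or less 9839 and 9542. A reciprocal overlap of 50% gave 43.4% and 44.9% shared, and both lists at 4-fold 73.95% and 73.98%. Differential peaks numbered 426 at adjusted p under 0.05 (224 higher, 202 lower), 175 at 2-fold (98 and 77) and 621 at p under 0.01 (297 and 324). At 2-fold the odds ratio for the 3′ UTR was 1.36 (Fisher's exact p = 0.353), with 175 peaks in place of 1206; whether their number or the stronger change is the cause was not tested. The odds ratio between m6A and RNA change ran from 3.39 to 11.0 over its alternatives, each of which shares the input libraries between both values.

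Comparing IP with input per gene, the motif search and the window around stop codons were not run. Without fragment counts, what depth limits is unknown.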

Other observations

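The tests within classes of RNA fold change, on libraries numbered 3, on the glycolytic share, without hypoxia library 3 and on KEGG pathways were chosen after the results they bear on were seen.

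Among KEGG pathways, genes lower in hypoxia were over-represented in aminoacyl-tRNA biosynthesis (23 of 40 genes, hypergeometric adjusted p = 0.000652; after median-ratio scaling 16 of 40, 0.000125). WARS1, which charges tryptophan tRNA, had 73.9 ± 2.55 FPKM in normoxia and 13.5 ± 2.32 in hypoxia (log2 fold change -2.38), and FARSA -2.30. In the proteasome 22 of 40 were lower (0.00111; after scaling 13 of 40, 0.00713), among them PSMB3 (131 ± 3.04 to 23.7 ± 3.96 FPKM, -2.43), PSMC4 (-1.62) and PSMD2 (-1.15). Genes higher in hypoxia were over-represented among neuroactive ligands and receptors (17 of 51, 5.99e-07, and after scaling 19 of 51, 2.27e-06). They included APLN, F2RL2 (1.94), NMB (1.49) and the vasodilator gene ADM (19.2 ± 2.65 to 66.6 ± 13.4 FPKM, 1.73). APLN, F2RL2 and NMB had 0.263, 0.0313 and 0.0549 FPKM in normoxia, so they passed the filter at 1 FPKM only through hypoxia. How much this filter adds to the over-representation was not tested. Unlike camera, the hypergeometric test makes no allowance for correlation between genes, so its p-values can be too small for genes that vary together. KIT, the receptor of stem cell factor, went from 12.3 ± 1.68 to 90.9 ± 20.1 FPKM (2.77). Genes with differential m6A passed in 0 of 322 pathways by this test (smallest adjusted p 1 and 0.304).

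14 genes were listed at 0 in each normoxia library and above 1 FPKM in each hypoxia library, among them CPNE6 and EPHA10, and 2 the reverse. EPHA10 was chosen after its values were seen, as were the pathway members above other than APLN. Of 93 ribosomal and proteasome genes 0 were listed at 0. 23 listed genes lie on chromosome Y, and 5 of them had at least 1 FPKM in all 6 libraries.

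Differential peaks lower in hypoxia lay in 3′ UTRs more often than higher ones. Within 10 classes of RNA fold change over 1090 peaks of tested genes the Mantel-Haenszel odds ratio was 2.77 (2.15 to 3.57), with 2.43 (1.73 to 3.41) for genes whose RNA did not pass and 3.26 (2.18 to 4.90) for those whose RNA passed, so the measured RNA change alone does not account for it. Among peaks with adjusted p under 0.05 it was 3.44 (2.27 to 5.25), which argues against weakly supported peaks as the whole cause, while at 2-fold or more it was 1.36 (0.707 to 2.62, Fisher's exact p = 0.353). The difference in enrichment between 3′ UTR and exonic peaks moved by -0.029 between lists (-0.10 to 0.01), which leaves a shift of enrichment across positions open. All of these intervals treat peaks as independent and do not measure the spread between libraries. No biological explanation was tested.

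Libraries numbered 3 of both conditions deviated from the other 2 along the same axis (correlation between conditions 0.697). In normoxia this was 1 end of a gradient. Normoxia library 1 deviated the opposite way (-0.712 with hypoxia library 3), and normoxia library 2 lay between (-0.0425). The axis of library 3 against the other 2 correlated with local gene density, a stand-in for GC content (rho 0.349 in normoxia and 0.512 in hypoxia). Sequence composition may therefore contribute. The 18 genes of G2 and mitosis were all below 0 on this axis (median -1.03), at percentile 0 of 10000 lists matched on density. Their estimated inter-gene correlation was 0.944, so lists of unrelated genes understate the spread of such a list. Fewer dividing cells may also contribute, but this percentile cannot decide. With density regressed out the correlation with gene span was -0.10, which leaves gene length open. The labels give no day or run that would tell these apart.

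Genes lower in hypoxia outnumbered those higher in the limma test. In the authors' deposited comparison the genes with a q-value under 0.05 were near even, 1236 higher and 1243 lower. After median-ratio scaling 52.4% of calls were lower, but scaling centres the genes by construction, so this cannot decide. Glycolytic transcripts took 1.57 ± 0.0849% of FPKM in normoxia and 7.35 ± 1.32% in hypoxia, which would shift all other genes by -0.087 (log2), less than the median of -0.26, and leaves part of it open. Without hypoxia library 3 73.6% of calls were lower, so that library alone does not account for it. Total RNA per cell was not analysed here, and a fall in most mRNAs cannot be told apart from a scaling effect.

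The 6 input libraries can be split 10 ways into 3 and 3, too few for a share under 0.05. For genes the real split gave 2699, matched by 1 of the 10 (itself), and the highest other 0 by limma, with up to 943 at an unadjusted p under 0.05. Each other split puts libraries of both conditions in both of its groups, so the difference between conditions enters its residual spread. The 0 calls are therefore no measure of what chance would give. For lists the real split gave 9, 3 of the 10 gave as many, and the highest other 10.

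A hypothesis was that peaks found in a single condition follow RNA level. Among genes with a tested RNA value, those with a peak in hypoxia alone (258 of 880) had a median RNA log2 fold change of -0.10 and those with a peak in normoxia alone (865 of 1435) -0.38, a difference of 0.28 (permutation p = 0.0001, the smallest the permutations can give), so peak detection may follow RNA level. A second hypothesis was that RNAs with a 3′ UTR peak in both lists fall more than RNAs without a peak. Within classes of RNA level the difference was 0.024, opposite in sign to the hypothesis and within the spread of the permutations (permutation p = 0.13), so it shows no such fall and leaves a small one open.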
